A study of Mus musculus with 18 samples.

How the data were processed

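Lungs of 18 BALB/c mice were profiled, each mouse on 1 Affymetrix mouse array with biotin-labelled cRNA. The only data were the deposited series table of 45101 probe sets on 18 arrays. The deposited values were taken as log2 signals, and each array has a median of exactly 0 over all probe sets. The sources used name neither the log base, nor the authors' software, nor how probes were summarised into probe sets. The log base was inferred from the hybridisation spike-ins, whose Cre minus BioB difference was 6.35 to 6.73 on every array. Per-array SD of the values was 2.74 to 3.18, no pair of arrays was identical, and each array was assigned to its group from the labels. Arrays carry no count depth; their number and the signal over background limit the precision.

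The platform annotation gave 1 gene for 34958 probe sets, several genes for 932 and none for 9160, and 64 probe sets were controls. Of the 1-gene probe sets 34754 matched a RefSeq gene by identifier, and symbols follow RefSeq. Coordinates are not given because each value belongs to a gene, not a position. A probe set was kept when it exceeded the 30th percentile of its array's non-control probe sets on at least 4 arrays, which left 34104. Each gene was represented by its kept probe set with the highest mean over all 18 arrays, which gave 14849 genes, 7119 of them with more than 1 kept probe set. Among genes called in the first comparison with more than 1 probe set (1858), 25 had probe sets called in both directions, and 16 of 1863 in the second. Of 157 named values 3 had a further kept probe set with the opposite sign, none of them called (Ighm in vehicle infected against non-infected lungs, and Sphk2 and Cxcl9 in co-immunized lungs at 7 days).

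A linear model of the 4 groups was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with a trend in the prior variance. The 5 comparisons were two-sided contrasts, with Benjamini-Hochberg adjustment over all genes within each; a gene was called at an adjusted p under 0.05. No covariate or block was used. Labels give the groups the same replicate numbers, but state nothing shared by animals with a number. The 38 gene lists were written from general knowledge and held 722 genes, of which 605 were measured. They were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. List members were also counted with p adjusted over the list alone. A list score is the mean over measured members of the log2 value minus the non-infected mean. Some genes stand in several lists, such as Lcn2 and Chil3.

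Comparisons, tests, filter, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took, for each comparison, the 5 higher and 5 lower called genes with the largest change and no overlap between groups, up to 3 of the largest called members of each list described (or its member with the highest mean where none passed), and a fixed set of genes (Il6, Il1b, Tnf, Il10, Ifng, Cxcl1, Cxcl2, Ccl2, Cxcl9, Cxcl10, S100a8, Saa3, Lcn2, Ighm, Jchain, Sftpc, Scgb1a1); the text may name fewer.

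Alternatives covered the filter (none, or the 50th percentile), quantile normalization, centring on kept probe sets, the choice or mean of probe sets, probe sets tested separately, the variance prior, array weights, fits of single group pairs, a 2-fold minimum, a replicate block, RNA quality as a covariate and leaving out each array. RNA quality was the log2 ratio of 3-prime to 5-prime control probe sets, with group means of 1.66 to 1.94. After the data were seen, alternatives were added that left out 4 arrays carrying thymocyte or skeletal muscle genes or used thymocyte, Glycam1 and skeletal muscle signals as 3 covariates. Overlaps of called genes were compared with independent lists, with 100 simulated sets without effects and with splits of the shared arrays.

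The procedure was tested on simulated data with the same arrays and 200 changed genes. Of genes changed by 1 on the log2 scale it recovered 69%, 65%, 73%, 66% and 70% in the 5 comparisons in the order of the report, and of those changed by 2 it recovered 91%, 92%, 94%, 91% and 95%. Unchanged genes made up 4.19%, 4.27%, 4.02%, 9.25% and 3.51% of the calls. The list that was moved was called in each comparison by each set test. Of 37 unmoved lists 0 were called, except 1 by fry in co-immunized 7 d against non-infected lungs. The simulated genes varied independently of each other. These counts therefore do not show how often lists of correlated genes are called without an effect.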

Results

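Lung RNA was measured on 18 one-colour Affymetrix mouse arrays, each from 1 female BALB/c mouse aged 8 weeks. The infection was a dose of 5000 CFU of serotype 3 Streptococcus pneumoniae, the pneumococcus. The co-immunized mice had received 0.5 ug of the capsular polysaccharide of that serotype together with 0.1 ug per g of lipopolysaccharide, a bacterial endotoxin, 5 days before infection, and the vehicle mice had received saline. The groups were 5 non-infected lungs and 5 vehicle infected lungs collected at 48 hours, 4 co-immunized infected lungs collected at 48 hours, and 4 co-immunized infected lungs collected at 7 days. After filtering, 14849 genes were tested, each through 1 probe set. Arrays give no count of molecules, so their number limits the precision. Log2 signals correlated at 0.923 or higher between arrays of a group, across genes, which are not independent replicates. The labels do not state the log base, which was inferred to be 2 from control probe sets. The values carry no detection calls, so signals under the 30th percentile of their array (-1.91 to -1.43), the level of the filter, count as weak. A fold change against weak signals has no exact size, and "raised" marks its value with such signals set to that percentile. Errors beside fold changes are standard errors from limma, and n stands for the arrays in the first and the second group named.

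**Figure D1:**
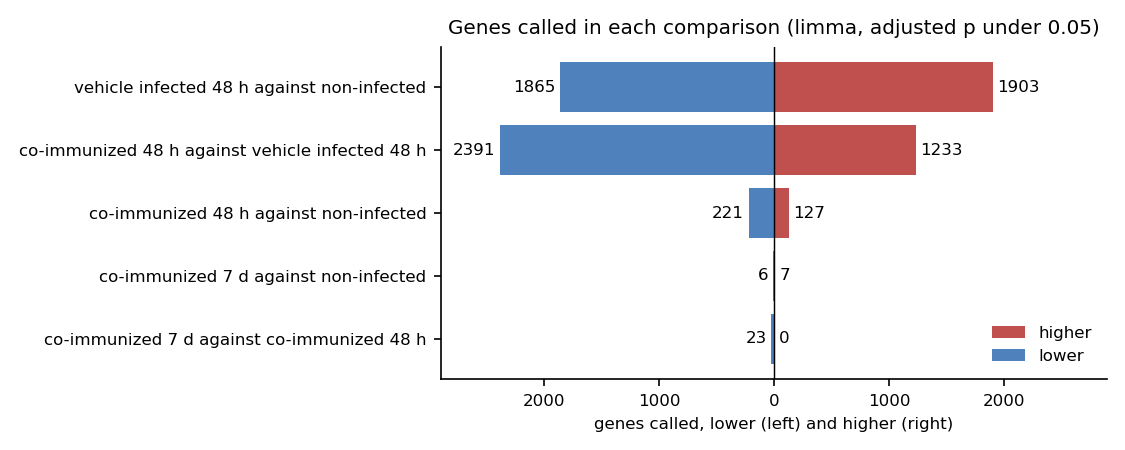
Number of genes called higher (right, red) and lower (left, blue) in each of the 5 comparisons, by limma at an adjusted p under 0.05. The pair of comparisons that use the vehicle infected lungs gave 3768 and 3624 genes, and the other 3 gave 348, 13 and 23.

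The effect of infection without immunization was read from vehicle infected against non-infected lungs at 48 hours (n = 5 and 5). The non-infected mice were mock-infected. The labels give no day of injection for them, so the vehicle injection may differ as well. In infected lungs all 21 type I interferon response genes rose, as did 20 of 22 interferon-gamma response genes, 14 of 17 neutrophil markers and 17 of 20 acute phase genes, while 8 of 13 smooth muscle and pericyte genes fell. These set calls held with an estimated correlation between genes. Among the genes with the largest measured rises were Acod1, which makes itaconate in activated macrophages (log2 fold change 7.26, SE 0.571), the interferon-induced T cell attractants Cxcl9 (7.22, SE 0.555) and Cxcl11 (6.91, SE 0.411), the neutrophil growth factor Csf3 (7.10, SE 0.854) and the neutrophil granule gene Ngp (6.76, SE 0.604). Non-infected signals of these genes were weak on 2 to 5 of the 5 arrays, and the raised values were 7.00, 6.87, 6.16, 4.08 and 6.41. Further called probe sets of Cxcl9 and Cxcl11 rose less, by 4.29 and 3.90. The largest measured falls were in the retinoic acid binding gene Crabp1 (-4.18, SE 0.442), Gsg1l (-3.75, SE 0.470), the carboxylesterase Ces2b (-3.57, SE 0.433), Gm19461 (-3.37, SE 0.613) and Lrrc17 (-3.07, SE 0.516). In infected lungs these 5 were weak on 4 or 5 of the 5 arrays, with raised values of -1.93, -0.37, -2.65, -0.78 and -1.16, so neither their sizes nor their order are settled. The adjusted p of these 10 genes was 0.000347 or lower.

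Among inflammatory cytokines and chemokines, 14 of 21 measured members rose and none fell, over all genes and adjusted over the list alone. Il6 rose by 4.87 (SE 1.08; 2.57 raised), Ccl2 by 4.70 (SE 0.697), Cxcl2 by 4.52 (SE 0.646), Cxcl1 by 3.85 (SE 0.475), Ifng by 2.06 (SE 0.363), Tnf by 1.61 (SE 0.260) and Il1b by 1.40 (SE 0.350). The set call of this list was lost with an estimated correlation (adjusted p = 0.056). All 21 measured type I interferon response genes rose, and 20 of 22 interferon-gamma response genes did, with the same numbers adjusted over the list alone. Cxcl10 rose by 5.75 (SE 0.359), the antiviral gene Mx1 by 3.92 (SE 0.235) and the interferon regulator Irf7 by 3.69 (SE 0.187). Neutrophil markers rose in 14 of 17 members by either adjustment, including the collagenase Mmp8 (6.08, SE 0.401; 5.18 raised) and the calprotectin subunit S100a8 (2.08, SE 0.221), which lay within 0.532 of the highest value of each vehicle array, so its rise can be compressed. Acute phase genes rose in 17 of 20 members; adjusted over the list alone, 17 rose and 1 fell. The serum amyloid genes Saa1 and Saa3 rose by 6.58 (SE 0.272) and 4.85 (SE 0.300), and Lcn2, which binds bacterial siderophores, by 2.24 (SE 0.235). Saa3 and Lcn2 lay within 0.54 and 1.01 of the highest value of each vehicle array, so the same limit holds for their rises. The set calls of the interferon, neutrophil and acute phase lists held with an estimated correlation.

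Glucocorticoid and metallothionein genes rose in 14 of 16 members by either adjustment, among them the steroid-induced genes Fkbp5 (4.16, SE 0.371) and Zbtb16 (4.03, SE 0.214) and the metallothionein Mt2 (3.03, SE 0.289). Pattern recognition and inflammasome genes rose in 16 of 21 members by either adjustment, with Mefv, the pyrin gene, at 2.93 (SE 0.202). Complement and Fc receptor genes rose in 15 of 20 members and 1 fell (16 and 1 adjusted over the list alone), with complement factor B (Cfb) at 4.04 (SE 0.297) and the IgG receptor Fcgr1 at 3.19 (SE 0.212). Monocyte and recruited macrophage genes rose in 13 of 21 members and 1 fell (15 and 1 adjusted over the list alone). Regulatory and checkpoint genes rose in 14 of 18 members by either adjustment, with Il10 at 3.07 (SE 0.678; 1.55 raised). The set calls of these lists held with an estimated correlation. NK and cytotoxic genes rose in 8 of 16 members (9 adjusted over the list alone), hypoxia and glycolysis genes in 10 of 18 and oxidative stress genes in 10 of 15, each the same adjusted over the list alone. Granzyme B (Gzmb) stood at 3.44 (SE 0.455), the glycolytic regulator Pfkfb3 at 2.12 (SE 0.190) and heme oxygenase (Hmox1) at 2.35 (SE 0.295). With an estimated correlation the set calls of these 3 lists were lost (adjusted p = 0.0886, 0.219 and 0.136). Cell cycle genes rose in 6 of 25 members by either adjustment, with the proliferation marker Mki67 at 1.54 (SE 0.280), and adjusted p = 0.533 for the list with an estimated correlation.

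Endothelial genes fell in 9 of 22 members and smooth muscle and pericyte genes in 8 of 13 (9 and 10 adjusted over the list alone). The VEGF receptor Kdr fell by 1.97 (SE 0.174), endomucin (Emcn) by 1.34 (SE 0.172) and calponin (Cnn1) by 1.59 (SE 0.236). The endothelial set call was lost with an estimated correlation (adjusted p = 0.395) and the smooth muscle one was kept. B cell genes fell in 11 of 18 members by either adjustment, with the IgE receptor Fcer2a down (-1.82, SE 0.348) and Ms4a1, the CD20 gene, down (-1.42, SE 0.374); adjusted p = 0.385 for the list with an estimated correlation. The B cell scores of the 5 vehicle arrays were -1.07, 0.00227, -0.317, -1.58 and -1.55, and the highest 2 came from replicates 2 and 3, in which Glycam1, a gene of lymph node venules, stood at 5.68 and 5.27 against -3.77 or lower in the other 3. Heart muscle genes fell in 6 of 14 members (7 adjusted over the list alone), with Actc1 down (-1.94, SE 0.235) and adjusted p = 0.5 for the list with an estimated correlation. Skeletal muscle genes stood apart on non-infected replicate 1 (mean log2 signal 4.26) and vehicle replicate 3 (3.86), and without the 4 arrays that carried such genes or thymocyte genes 10 heart muscle genes fell.

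Alveolar type 2 and club and ciliated cell lists were not called. In the first, 3 of 18 members fell, and in the second 1 of 19 rose and 1 fell, with the same numbers adjusted over the list alone. Surfactant protein C (Sftpc) differed by 0.08 (SE 0.222) and the club cell secretoglobin Scgb1a1 by 0.04 (SE 0.236), and both signs changed with the scaling. Their signals lay at or within 0.701 of the highest value of each vehicle array, where a rise is hard to measure. T cell genes had a median log2 fold change of -0.02, with 2 of 20 higher (1 adjusted over the list alone) and no set call. Ighm (-0.58, SE 0.325) and Jchain (-0.49, SE 0.214) did not pass. The 8 probe sets of Ighm ranged from -0.86 to 0.48, with 1 called lower and 5 of the opposite sign. The clock-related genes Nfil3 and Per1, which also respond to stress signals, rose, Nfil3 by 2.43 (SE 0.328) and Per1 by 2.30 (SE 0.386). Values of the groups did not overlap for the called genes given here, except Il6, Cxcl2, Il10, Fcer2a, Ms4a1 and Nfil3.

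In all, 3768 genes were called, 1903 higher and 1865 lower, of which 1313 also differed at least 2-fold. With quantile normalization 40.1% of the called genes were higher, against 50.5% as first computed. Camera called 22 of the 38 lists, and 11 with an estimated correlation.

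**Figure D2:**
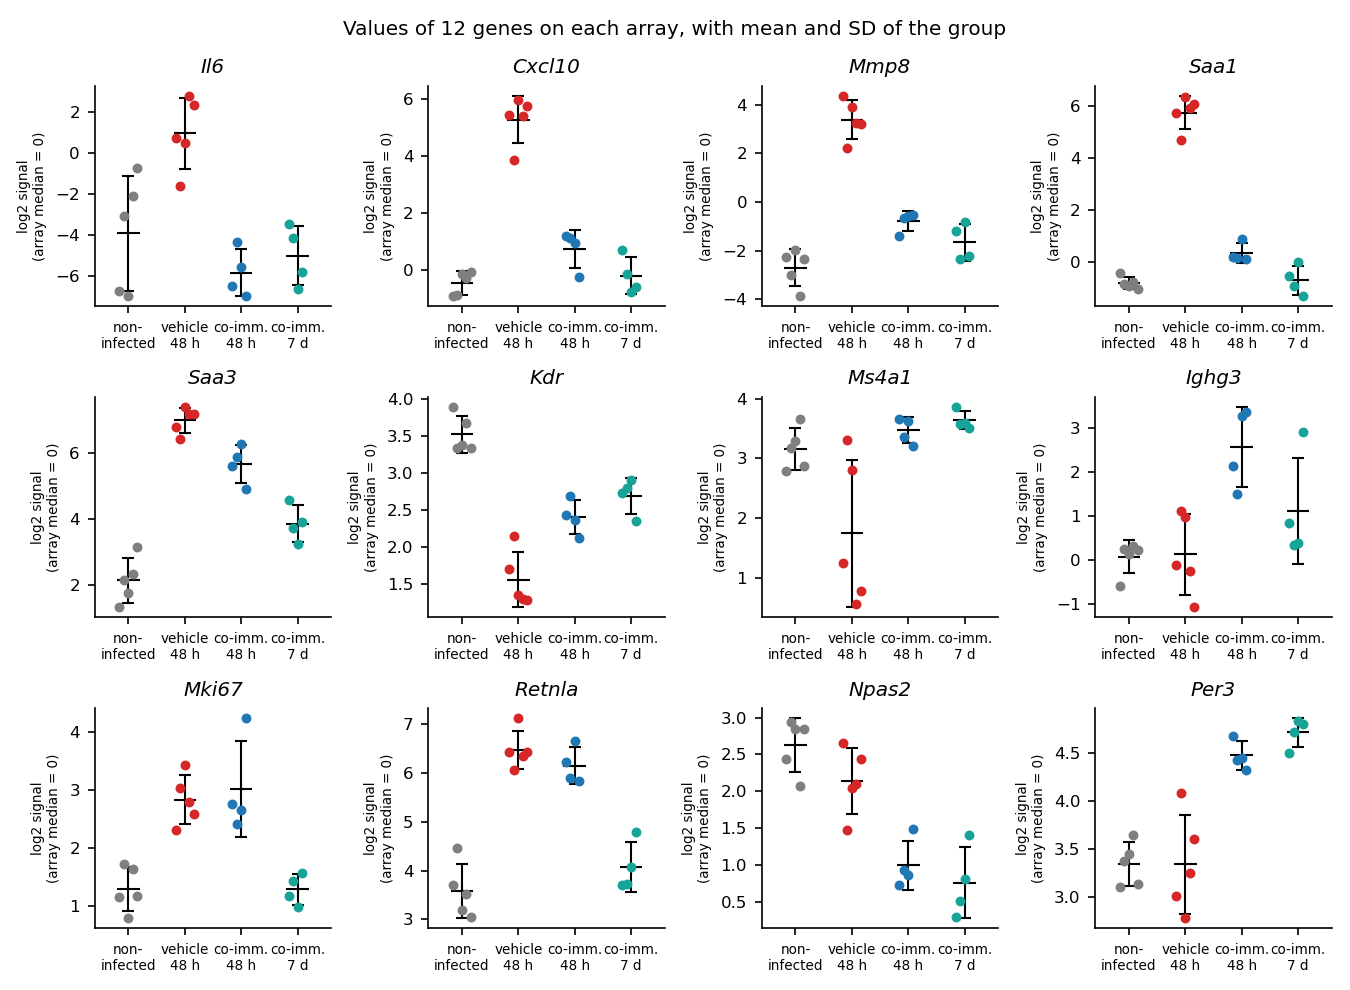
Log2 signal of 12 genes on each array (points), with the mean (line) and SD (bar) of the 4 groups; each array's median over all probe sets is 0. Cxcl10, Mmp8 and Saa1 were far higher in vehicle infected lungs than in the other groups, with mean Cxcl10 signals of 5.28 against 0.736 in co-immunized lungs at 48 hours.

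The effect of earlier co-immunization was read from co-immunized against vehicle infected lungs at 48 hours (n = 4 and 5). The same test asks whether the change from non-infected lungs differed between immunized and vehicle mice. In co-immunized lungs all 21 type I interferon response genes, 21 of 22 interferon-gamma response genes, 13 of 17 neutrophil markers, 17 of 20 acute phase genes and all 16 glucocorticoid and metallothionein genes were lower, and 15 of 18 B cell genes were higher. None of these set calls held with an estimated correlation (adjusted p = 0.0692 for each lower list and 0.134 for B cells). The largest measured falls were in Il6 (-6.78, SE 1.15), Csf3 (-5.92, SE 0.906), the serum amyloid genes Saa2 (-5.76, SE 0.519) and Saa1 (-5.44, SE 0.288) and the hypoxia-related factor Hif3a (-5.42, SE 0.485). Co-immunized signals of Il6, Csf3 and Hif3a were weak on 4, 3 and 2 of the 4 arrays, with raised values of -2.75, -4.06 and -4.70, while Saa1 and Saa2 were above that level throughout. The 3 probe sets of Hif3a, all called, ranged from -5.42 to -1.52, so the size of its fall is not settled. The largest measured rises were in Cthrc1 (3.54, SE 0.702), Gsg1l (3.44, SE 0.498), Crabp1 (3.03, SE 0.469), Gm32688 (2.93, SE 0.623) and Lrrc17 (2.89, SE 0.547), with an adjusted p of 0.00193 or lower for all 10. In vehicle lungs these 5 were weak on 4 or 5 of the 5 arrays, and the raised values were 1.01, 0.26, 0.79, 0.64 and 0.98, so the order of the rises is not settled.

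All 21 type I interferon response genes were lower, as were 21 of 22 interferon-gamma response genes, with the same numbers adjusted over the list alone. Cxcl10 fell by 4.54 (SE 0.381), Cxcl9 by 4.28 (SE 0.588), Oasl1 by 3.50 (SE 0.285) and Ifit1 by 3.49 (SE 0.229). Cytokines and chemokines were lower in 15 of 21 members (16 adjusted over the list alone) and neutrophil markers in 13 of 17 (14). Il10 fell by 4.47 (SE 0.719; -1.54 raised), Ccl2 by 4.24 (SE 0.739), Cxcl2 by 4.23 (SE 0.686), Cxcl1 by 3.04 (SE 0.504), Ifng by 1.97 (SE 0.386), Il1b by 1.63 (SE 0.371) and Tnf by 1.26 (SE 0.276). Mmp8 fell by 4.17 (SE 0.426) and S100a8 by 1.99 (SE 0.235). Acute phase genes were lower in 17 of 20 members (17 lower and 1 higher adjusted over the list alone), and Saa3 and Lcn2 fell by 1.33 (SE 0.318) and 1.12 (SE 0.249). Vehicle signals of S100a8, Saa3 and Lcn2 lay within 0.532, 0.54 and 1.01 of the highest value of each array, so these falls can be compressed. All 16 glucocorticoid and metallothionein genes were lower by either adjustment, with Zbtb16 down (-4.36, SE 0.227) and Fkbp5 down (-3.51, SE 0.393). Monocyte and recruited macrophage genes were lower in 12 of 21 members and higher in 1 (13 and 1 adjusted over the list alone). None of these set calls held with an estimated correlation (adjusted p = 0.0692 for the interferon, neutrophil, acute phase and glucocorticoid lists, 0.113 for cytokines and 0.0722 for monocytes).

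B cell genes were higher in 15 of 18 members by either adjustment, with Fcer2a at 2.18 (SE 0.369) and Ms4a1 at 1.73 (SE 0.397). Immunoglobulin and plasma cell genes were higher in 7 of 17 members and lower in 2, by either adjustment. The heavy chain gene of IgG3, Ighg3, rose by 2.43 (SE 0.499), the lambda light chain gene Iglv1 by 2.03 (SE 0.272), Ighm by 1.51 (SE 0.345) and the joining chain gene Jchain by 0.88 (SE 0.227). The adjusted p with an estimated correlation was 0.134 and 0.0692 for these lists. The values of Ighg3, Iglv1 and Ighm are the highest among their probe sets, and the lowest were 0.97, 1.05 and 0.44. All kept probe sets of Ighg3 and Iglv1 were called. Of the 8 probe sets of Ighm 2 passed, and it did not pass without probe sets that can cross-hybridize (adjusted p up to 0.27 over its alternatives). Glycam1 was also high on co-immunized 48 h replicates 1, 3 and 4 (5.27, 6.12 and 2.78) and low on replicate 2 (-1.28), where Ighg3 stood at 1.5 against 2.14, 3.27 and 3.36.

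T cell genes were higher in 12 of 20 members (15 higher and 1 lower adjusted over the list alone) and cell cycle genes in 4 of 25 by either adjustment. Here Cd8a stood at 1.78 (SE 0.568), with 2 of its 5 probe sets called, Cd3g at 1.49 (SE 0.415) and the mitotic gene Birc5 at 0.82 (SE 0.268). The thymocyte genes Dntt, Ptcra and Themis had a mean signal of 3.7 on co-immunized 48 h replicate 4 and at most -1.14 on any other array. Without that replicate 2 T cell genes were higher and 1 lower, no cell cycle gene passed, and Cd8a, Cd3g and Birc5 were no longer called. Cd8a and Birc5 were also lost without vehicle replicate 4 or 5, and Cd8a without vehicle replicate 1, at adjusted p up to 0.146 for Birc5 and 0.125 for Cd8a. With an estimated correlation the adjusted p was 0.242 for the T cell and 0.318 for the cell cycle list.

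Smooth muscle and pericyte genes were higher in 6 of 13 members and lower in 1 (8 and 1 adjusted over the list alone), with Cnn1 at 1.62 (SE 0.250) and adjusted p = 0.0692 for the list with an estimated correlation. Club and ciliated cell genes were higher in 7 of 19 members and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation). Heart muscle genes were higher in 8 of 14 by either adjustment, with Actc1 at 1.93 (SE 0.249) and adjusted p = 0.217 with an estimated correlation; skeletal muscle genes stood at 3.94 on co-immunized 48 h replicate 2. Endothelial genes went both ways, 3 higher and 3 lower of 22 (7 and 4 adjusted over the list alone), with Kdr up by 0.85 (SE 0.184), a median of -0.17, a mean of 0.0299 and no set call. No alveolar type 2 gene of 18 passed by either adjustment. The clock-related genes Nfil3 (-3.60, SE 0.348) and Dbp (1.70, SE 0.352) also differed.

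In all, 3624 genes were called, 1233 higher and 2391 lower, of which 1246 differed at least 2-fold. The median log2 fold change of all genes was -0.1057 here and 0.0599 with quantile normalization, and the direction of small changes depended on it. The share of called genes that were higher was 34% as first computed, 48.3% with arrays centred on the kept probe sets and 58.7% with quantile normalization. The count was 2065 from the arrays of these groups alone and 2102 with 3 covariates for thymocyte, Glycam1 and skeletal muscle signals, and 0 of the 23 set calls held with an estimated correlation (fry, which tests a list on its own, called 22 lists but not the cell cycle or the club and ciliated list, at adjusted p = 0.083 and 0.057).

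Of the 3768 genes that differed between vehicle infected and non-infected lungs, 2251 (59.7%) differed in the opposite direction between co-immunized and vehicle infected lungs, and 1 in the same direction. Independent lists of these sizes would share 461. Both comparisons use the vehicle arrays, and in 100 simulated sets without any effect the median shared count was 0 and the highest 1. Few genes pass in such sets, so these counts do not show how much the shared arrays add. When the vehicle arrays were split between the comparisons, the count was 721 to 1683 with a median of 1451.5 over 20 splits. Across genes, the covariance between the infection change and the negative of the immunization change was 0.403 against 0.0405 in the simulations, and the correlation 0.835 against 0.474. The 1903 genes higher in vehicle infected lungs had a median log2 fold change of 0.81 there against non-infected lungs. In co-immunized lungs at 48 hours it was 0.04. The 1865 lower genes had medians of -0.77 and -0.30. These genes were chosen by their change in vehicle infected lungs, which can enlarge the medians there. Over all genes the co-immunized median against non-infected lungs was -0.0978, and -0.0101 with quantile normalization. How far 0.04 and -0.30 each lie from 0 thus depends in part on the scaling.

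**Figure D3:**
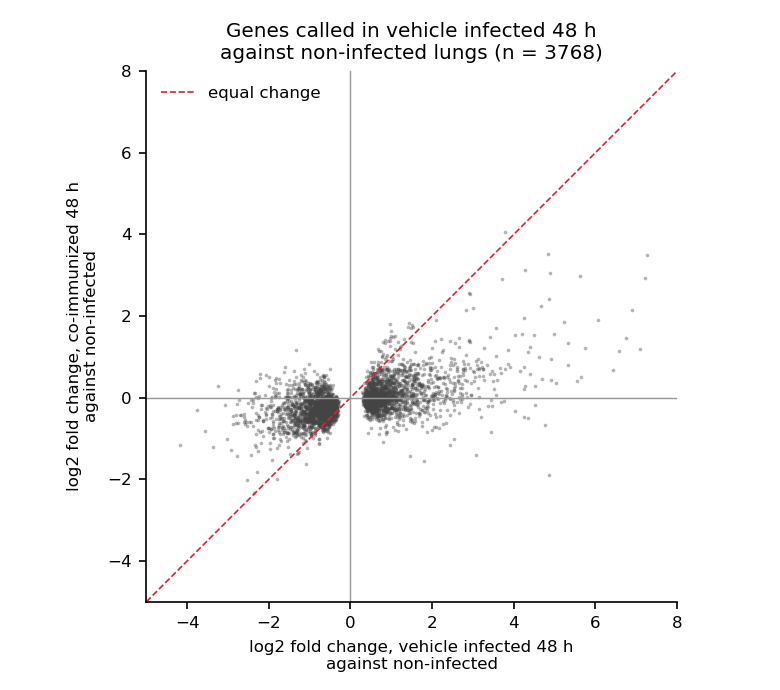
Log2 fold change against non-infected lungs at 48 hours in vehicle infected lungs (horizontal) and in co-immunized infected lungs (vertical), for the 3768 genes called in vehicle infected lungs (1 point each). Most points lie nearer to 0 on the vertical axis than the dashed line of equal change. The medians were 0.81 and 0.04 for the higher genes. Both axes share the non-infected arrays, and the genes were chosen by their horizontal values.

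How far co-immunized infected lungs stood from non-infected lungs at 48 hours was read with immunization and infection differing together (n = 4 and 5). Co-immunized lungs had higher signals of Saa3 (3.52, SE 0.318), of the macrophage gene Retnla (2.57, SE 0.272) and of Cxcl9 (2.94, SE 0.588), and a higher signal of the mitotic gene Birc5 (1.80, SE 0.268). The matrix protein Spon2 (-1.99, SE 0.257) and the clock gene Npas2 (-1.63, SE 0.249) were lower and the clock gene Per2 was higher (1.45, SE 0.246). These 7 kept their calls under each alternative tried, but further probe sets of Npas2 (-0.13), Cxcl9 (1.01) and Spon2 (-0.96) and 1 of the 3 of Per2 did not pass. Retnla was as high without immunization, with mean signals of 6.48 in vehicle infected, 6.15 in co-immunized and 3.58 in non-infected lungs. Other measured rises were in Klk1b27 (4.06, SE 0.621), a member of a family of near-identical kallikrein genes that 1 probe set may not tell apart, Acod1 (3.49, SE 0.605), the ubiquitin-like gene Ubd (3.06, SE 0.665) and the acute phase gene Orm2 (2.99, SE 0.668), and a further fall was in Wnt7a (-1.62, SE 0.358). Klk1b27 was weak on all 5 non-infected arrays and on 2 of the 4 co-immunized ones, with a raised value of 0.37, so its size is not known; the raised values of Acod1, Ubd, Orm2 and Cxcl9 were 3.23, 2.86, 1.32 and 2.59.

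Acute phase genes were higher in 5 of 20 members by either adjustment, with Lcn2 at 1.12 (SE 0.249), and interferon-gamma response genes in 3 of 22 (5 adjusted over the list alone), with Cxcl11 at 2.16 (SE 0.436; 1.41 raised; 0.93 in a further probe set that did not pass). Type I interferon response genes were higher in 1 of 21 (8 higher and 1 lower adjusted over the list alone), neutrophil markers in 2 of 17 (3 adjusted over the list alone), and cytokines and chemokines in 1 of 21 by either adjustment. Monocyte and recruited macrophage genes were higher in 5 of 21 (8 adjusted over the list alone), with Ms4a6d at 1.04 (SE 0.191). Also higher were the chemokine Ccl8 (1.46, SE 0.294) and the airway mucin Muc5b (1.72, SE 0.382), the latter among 2 of 13 IL-17 and epithelial defence genes (6 adjusted over the list alone). The mean score of that list was 0.911 in these lungs and 1.1 in vehicle infected lungs, so it was not particular to co-immunized mice. Il6 (-1.90, SE 1.15), Tnf (0.35, SE 0.276), Cxcl10 (1.21, SE 0.381) and S100a8 (0.09, SE 0.235) did not pass. With an estimated correlation the adjusted p of these lists was 0.155, 0.254, 0.328, 0.28, 0.373, 0.0661 and 0.144, in the order given.

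Cell cycle genes were higher in 11 of 25 members (19 adjusted over the list alone), with Mki67 at 1.72 (SE 0.297), a list median of 1.01 and adjusted p = 0.0661 with an estimated correlation. The cell cycle scores of the 4 co-immunized arrays were 0.772, 0.578, 0.587 and 1.86, against at most 0.227 in non-infected lungs. The highest was replicate 4, the array with thymocyte genes, and without it 5 members were higher and the median was 0.62. No T cell gene passed over all genes, and 12 of 20 were higher adjusted over the list alone (adjusted p = 0.144 with an estimated correlation); the T cell score of replicate 4 was 2.18. B cell genes had a median of 0.37, with no member passing by either adjustment (adjusted p = 0.328 with an estimated correlation). Of 17 immunoglobulin and plasma cell genes 2 were higher (2 higher and 1 lower adjusted over the list alone), Ighg3 (2.49, SE 0.499; 0.55 in a further probe set that did not pass) and Mzb1 (0.70, SE 0.169), and adjusted p = 0.144 with an estimated correlation. Ighm (0.93, SE 0.345) and Jchain (0.38, SE 0.227) did not pass.

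**Figure D4:**
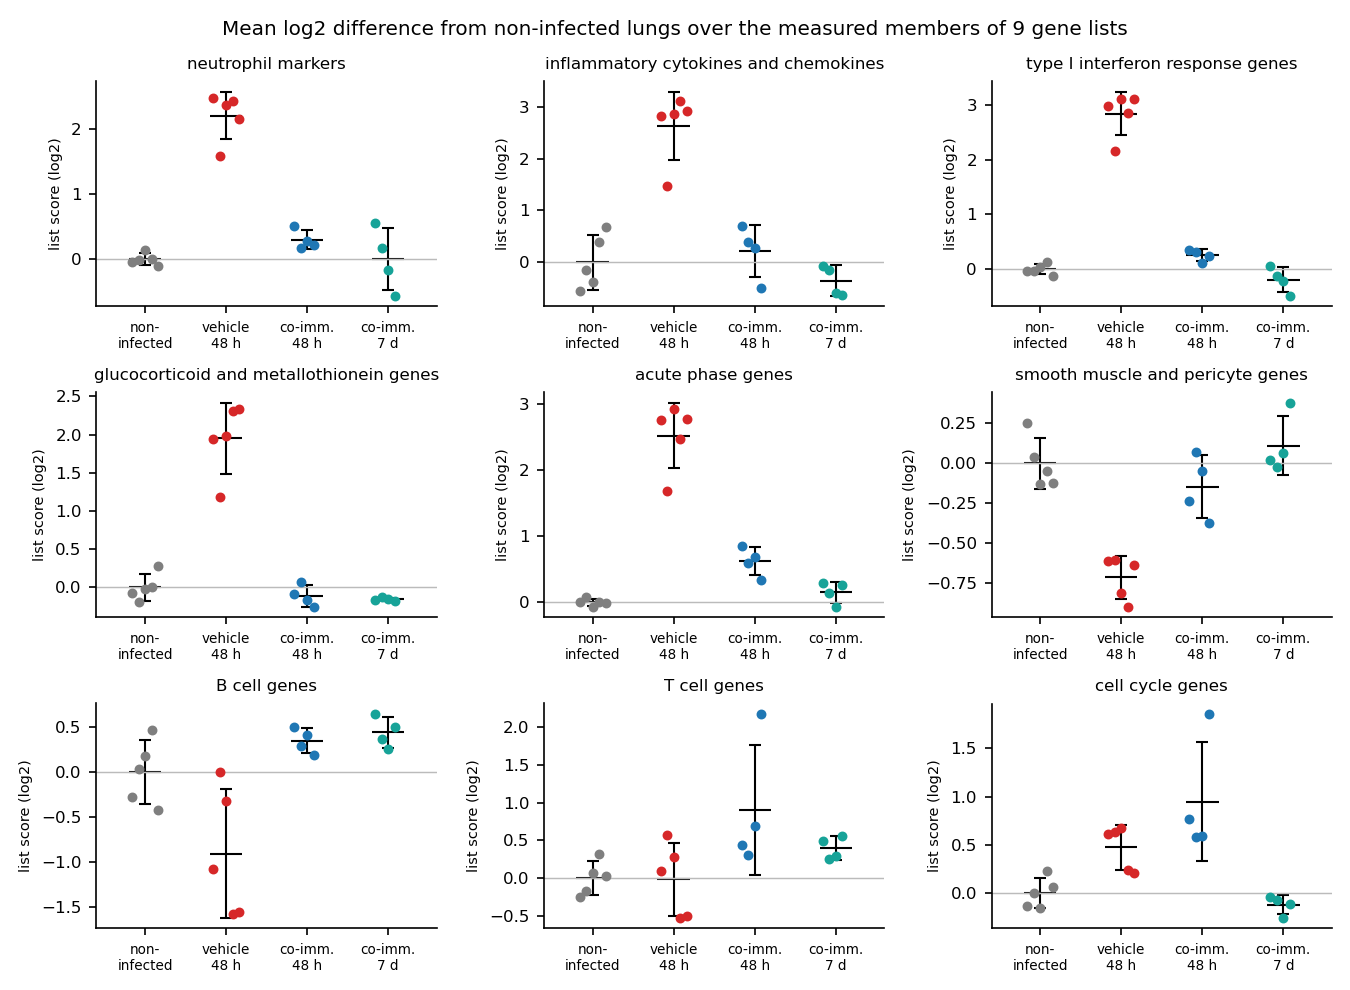
List score, the mean over measured members of the log2 signal minus the non-infected mean, on each array (points) with group mean (line) and SD (bar), for 9 gene lists. The T cell and cell cycle panels hold a co-immunized 48 h array, replicate 4, far above the rest, with scores of 2.18 and 1.86.

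Alveolar type 1 cell genes were lower in 5 of 17 members (11 adjusted over the list alone) and endothelial genes in 3 of 22 (6), including the basement membrane collagen Col4a3 (-1.38, SE 0.307), Kdr (-1.12, SE 0.184) and Emcn (-0.88, SE 0.182). Their adjusted p with an estimated correlation was 0.265 and 0.254. Of 16 clock genes 3 were higher and 3 lower (6 and 4 adjusted over the list alone), with Dbp at 1.59 (SE 0.352) and adjusted p = 0.28 for the list with an estimated correlation.

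In all, 348 genes were called, 127 higher and 221 lower, and 110 differed at least 2-fold. Of the called genes 36.5% were higher, against 49.4% with quantile normalization and 46.4% with arrays centred on the kept probe sets, and the balance turned in other settings. At 2-fold or more 80 were higher and 30 lower, without co-immunized replicate 4 the numbers were 30 and 12, without replicate 3 they were 63 and 35, and with the 3 tissue covariates 14 and 3. The count was 42 without co-immunized 48 h replicate 4, 98 without co-immunized replicate 3 and 155 without replicate 1, and 63, 87, 131 and 196 without non-infected replicates 5, 3, 4 and 2. It was 36 without the 4 arrays with thymocyte or skeletal muscle genes, 17 with the 3 tissue covariates, 160 without a trend in the prior variance, 632 with RNA quality as a covariate, 1344 with array weights and 1382 from the arrays of these groups alone. Without 1 array the calls were lost for Ubd, Orm2, Wnt7a, Cxcl11, Muc5b, Lcn2, Ighg3, Mzb1, Emcn, Col4a3, Ms4a6d and Dbp, at adjusted p up to 0.131 and with the same sign; for Ighg3 this happened without co-immunized replicate 3 or 4. For Cxcl11 and Ms4a6d it happened without replicate 4. Cytokines and chemokines lost their set call without co-immunized replicate 1 (median -0.01, adjusted p = 0.104) and with quantile normalization (adjusted p = 0.103). Of the 29 lists called, 0 held with an estimated correlation and fry called 2.

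Of the 348 genes, 214 (61.5%) changed in the same direction in vehicle infected lungs and 4 in the opposite one. Independent lists would share 44. The simulations without effect, in which few genes pass, had a median of 0 and a highest of 1. Splitting the non-infected arrays between the comparisons, which leaves fewer of them in each, gave 2 to 51 with a median of 11. The covariance of the fold changes was 0.104 against 0.0403 in the simulations, but their correlation, 0.364, lay under the 0.474 of the simulations.

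Co-immunized lungs at 7 days were set against non-infected lungs (n = 4 and 5), which had been collected at 48 hours, so time differed as well. Of the 13 genes that passed, 7 were clock genes. Higher were Dbp (1.87, SE 0.352), Per2 (1.58, SE 0.246), Hlf (1.45, SE 0.248) and Per3 (1.38, SE 0.195), and lower were Npas2 (-1.87, SE 0.249), Nfil3 (-1.80, SE 0.348) and Arntl (-1.73, SE 0.232), so that 4 of 16 clock genes rose and 3 fell (7 and 4 adjusted over the list alone). Dbp, Hlf and the Per genes are on the output and repressor side of the clock, while Arntl and Npas2 code for its activators. The other 6 genes were Klk1b27 (3.70, SE 0.621), the sphingosine kinase Sphk2 (2.45, SE 0.337) and Saa3 (1.72, SE 0.318), which rose, and the histone gene H3f3b (-2.46, SE 0.422), Ndnf (-1.80, SE 0.323) and Spon2 (-1.51, SE 0.257), which fell. Klk1b27 was weak on all 5 non-infected and 2 of the 4 co-immunized arrays (0.27 raised). Hlf, Per3 and Spon2 lay outside the rule for naming genes and were chosen after their values were seen.

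The set call of the clock list was lost with an estimated correlation (adjusted p = 0.54). Further probe sets of Sphk2 (-0.02), Arntl (-0.18), Npas2 (-0.34), Ndnf (-0.91), Spon2 (-1.35) and Hlf (0.82) did not pass, so these calls rest on 1 probe set each; of the 3 of Per2, 1 did not pass. Immunoglobulin and plasma cell genes had a median of 0.27, and their set call held with an estimated correlation (adjusted p = 0.0129). None of the 17 passed over all genes and 5 were higher adjusted over the list alone; Jchain stood at 1.08 (SE 0.227, adjusted p = 0.099) and Ighm at 1.21 (SE 0.345, adjusted p = 0.389). B cell genes had a median of 0.47 and no called member by either adjustment, and platelet genes a median of 0.47 with 0 of 10 called over all genes and 4 higher adjusted over the list alone; both set calls were lost with an estimated correlation (adjusted p = 0.54 and 0.267). Glycam1 stood at 5.83 on 7 d replicate 4 and at -2.92 or lower on the other 3 arrays, and Ighg3 at 2.91 against 0.84 or lower. No neutrophil, type I interferon or cell cycle gene passed by either adjustment, with list medians of 0.03, -0.23 and -0.11, and Saa3 was the 1 acute phase gene that did (2 of 20 adjusted over the list alone). Of these lists camera called the interferon list lower and the acute phase list higher, and both were lost with an estimated correlation (adjusted p = 0.791 and 0.664) and without 4 and 7 single arrays; the acute phase call was also lost with quantile normalization or without the filter (adjusted p = 0.0535 and 0.231). Cxcl9 did not pass (1.34, SE 0.588).

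The count of 13, with 7 higher and 6 lower, stood beside 1237 genes at an unadjusted p under 0.05. It fell to 4 without 7 d replicate 4, 6 without 7 d replicate 1, 7 without 7 d replicate 2, non-infected replicate 2 or non-infected replicate 3, and 8 without 7 d replicate 3 or non-infected replicate 5; it was 8 without a trend, 20 with RNA quality as a covariate, 21 with quantile normalization or the tissue covariates, 22 from these groups alone and 65 with array weights. Npas2, Arntl, Per3 and Sphk2 kept their calls without any single array, Per2 lost it without 7 d replicate 4 (adjusted p = 0.0648) and Klk1b27 without 7 d replicate 1 or 4, while Dbp, Saa3, H3f3b, Nfil3, Ndnf, Spon2 and Hlf lost theirs without 5 or more of the 9 arrays. Of the 17 lists called, 1 held with an estimated correlation. Of the 13 genes, 10 had changed in the same direction in co-immunized lungs at 48 hours. Independent lists would share 0.149, and the simulations, in which few genes pass, shared 0. With the non-infected arrays split between the comparisons, the shared count was 0 to 2, with a median of 0 over 20 splits. The overlap of 10 was thus not seen without shared arrays, though fewer arrays were left in each comparison.

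The change with time in co-immunized lungs was read from 7 days against 48 hours (n = 4 and 4). All 23 genes called were lower at 7 days. Retnla fell by 2.08 (SE 0.287) and Saa3 by 1.80 (SE 0.336), and mitotic genes fell together, with Cenpf down (-1.96, SE 0.381), Kif2c down (-1.88, SE 0.331), Shcbp1 down (-1.88, SE 0.371), Nusap1 down (-1.80, SE 0.313), Birc5 down (-1.76, SE 0.283) and Mki67 down (-1.73, SE 0.313). On co-immunized 48 h replicate 4, the array with thymocyte genes, Nusap1 stood at 3.49 against 1.39 to 1.74 on the others of its group. Birc5 (4.48) and Mki67 (4.25) were also highest there, so that array enlarges the falls of these genes. The macrophage gene Ms4a6d fell by 1.07 (SE 0.201).

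Cell cycle genes were lower in 6 of 25 members (21 adjusted over the list alone) with a median of -1.08, and monocyte and recruited macrophage genes in 1 of 21 (5 adjusted over the list alone) with a median of -0.52. Both set calls held with an estimated correlation (adjusted p = 0.00823 for each). Without co-immunized 48 h replicate 4, the array with thymocyte genes, 5 cell cycle genes were lower and the median was -0.74. Type I interferon response genes had a median of -0.38 with none of 21 called over all genes and 8 lower adjusted over the list alone, and T cell genes a median of -0.50 with none of 20 called by either adjustment. Their set calls were lost with an estimated correlation (adjusted p = 0.104 and 0.205), the T cell one also without co-immunized 48 h replicate 4 (median -0.12, adjusted p = 0.103). Clock genes did not differ as a list (median 0.20, adjusted p = 0.56), with no member called by either adjustment. Lcn2 (-0.96, SE 0.263) and Cxcl9 (-1.60, SE 0.620) did not pass.

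The count of 23 stood beside 778 genes at an unadjusted p under 0.05, and 2 of the 24 lists called held with an estimated correlation. It was 1 without 7 d replicate 3, 9 without 7 d replicate 1 or 2, 12 without 7 d replicate 4, 8 and 11 without co-immunized 48 h replicates 1 and 4, 8 without the 4 arrays with other-tissue genes, 2 with the tissue covariates or from these groups alone, 11 without a trend, 14 with the mean of a gene's probe sets and 110 with array weights. Retnla was called under each alternative. Birc5 lost its call without 7 d replicate 3 (adjusted p = 0.0523), and Cenpf, Kif2c, Shcbp1, Saa3, Ms4a6d, Nusap1 and Mki67 lost theirs without 3 to 7 of the 8 arrays, with the same sign. Further probe sets of Kif2c (-0.10), Cenpf (-1.50) and Ms4a6d (-1.17) did not pass.

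**Figure D5:**
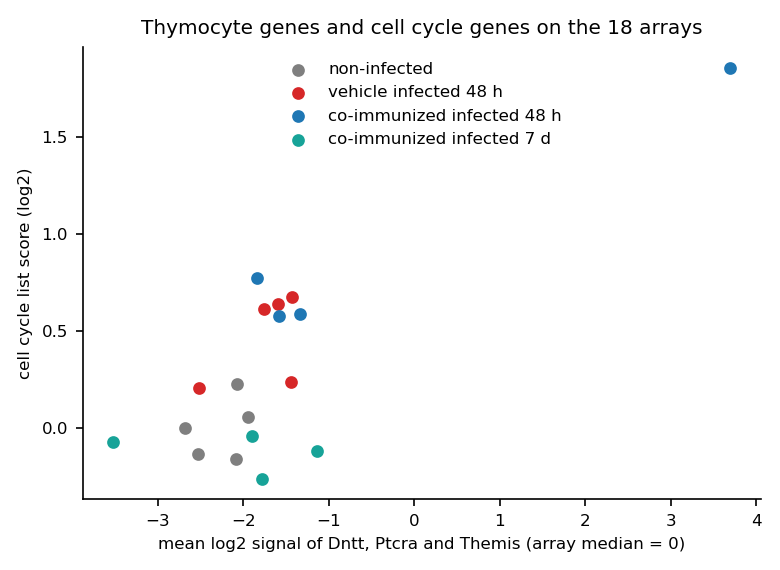
Mean log2 signal of the thymocyte genes Dntt, Ptcra and Themis (horizontal) and cell cycle list score (vertical) on each of the 18 arrays, coloured by group. Co-immunized 48 h replicate 4 stands apart at 3.7 and 1.86, and the other 3 arrays of its group score 0.578 to 0.772 at thymocyte signals of -1.34 or lower.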

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

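The tests of thymus tissue, lymph node tissue, hour of collection, RNA quality and infection alone in this part were chosen after the result was seen; the counts over other splits of the arrays and the tests of differences between groups were planned beforehand.

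The genes named and list scores described made 320 sets of values, 1 per group compared, and in 31 of them 1 array lay far from the others of its group by Dixon's ratio of its gap to the range; chance gives about 1 in 20 (16). Vehicle replicate 2 accounts for 16. It lay below the other 4 vehicle arrays for Acod1 (ratio 0.725), Cxcl10 (0.735), Cxcl1 (0.79), Mx1 (0.725), Hmox1 (0.754), Nfil3 (0.771), Oasl1 (0.791), Tnfaip3 (0.728), Timp1 (0.739) and Lox (0.722), and above them for Ces2b (0.729). Its scores were also low for cytokines and chemokines (1.48 against 2.82 to 3.10, ratio 0.825), type I interferon (0.743), hypoxia and glycolysis (0.873), oxidative stress (0.783) and NF-kB feedback genes (0.786). Non-infected replicate 1 was low for Cfb (0.79), Ighg3 (0.795), Selp (0.783) and the scores of pattern recognition (0.768), complement and Fc receptor (0.73) and clock genes (0.769). Non-infected replicate 5 was high for Acod1 (0.822) and low for Irf7 (0.918). Co-immunized 48 h replicate 4 was high for Cd8a (0.846), Cd3g (0.872), Nusap1 (0.835) and the cell cycle score (0.848). Co-immunized 48 h replicate 1 was low for Mmp8 (0.857), replicate 3 high for Saa1 (0.89), and 7 d replicate 4 high for the immunoglobulin and plasma cell score (0.836).

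The change from non-infected lungs at 48 hours differed between co-immunized and vehicle mice for 3624 genes, and in co-immunized mice it differed between 7 days and 48 hours for 23 genes, each by limma's test of the difference. Only the real split, 1 of the 100 drawn, gave as many genes in vehicle infected against non-infected (3768, highest other 2133), co-immunized against vehicle infected (3624, highest other 3461), co-immunized 48 h against non-infected (348, highest other 4) and co-immunized 7 d against non-infected lungs (13, highest other 2), and 1 of 35 in 7 d against 48 h (23, highest other 1). No other split reached these counts, but with 100 splits drawn the share cannot fall below 1 in 100, or 1 in 35 in the last comparison. The highest other split of the first pair put 1 array of each group in the other, vehicle replicate 2 and non-infected replicate 5, and that of the second put vehicle replicate 3 with the co-immunized arrays. For lists called by camera, 21 of 100 splits gave as many as the 22 of the first comparison (highest other 27) and 13 of 100 as many as the 23 of the second (highest other 25), so chance is not excluded for these counts. For the other 3 comparisons only the real split gave as many, 29 (highest other 28), 17 (highest other 16) and, of 35 splits, 24 (highest other 23). The other splits called a median of 18, 14, 11, 8 and 11 lists in the 5 comparisons, in the order of the report.

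In co-immunized 48 h against non-infected lungs 11 of 25 cell cycle genes were higher, 5 without replicate 4, and the set call was lost with an estimated correlation (adjusted p = 0.0661). On replicate 4 the thymocyte genes Dntt, Ptcra and Themis averaged 4.84 above the next highest array, so thymus tissue in that sample may add to its cell cycle score of 1.86. Thymus tissue as the source for replicates 1 to 3 is argued against, since their thymocyte signals lay at least 2.75 below the level that their scores would need at the ratio of replicate 4 (largest difference -2.75, SD among non-infected arrays 0.322). Infection with or without immunization stays open, since the list median in vehicle infected against non-infected lungs was 0.375 but its set call was lost with an estimated correlation (adjusted p = 0.533). The scores of replicates 1 to 3 (0.578 to 0.772) overlapped those of the vehicle arrays (0.206 to 0.677), and without replicate 4 no member passed against vehicle infected lungs.

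Ighg3 was higher in co-immunized 48 h than in non-infected lungs, and Glycam1 was high on 3 of those 4 arrays. With Glycam1 as a covariate the log2 fold change was 1.67 (SE 0.34, adjusted p = 0.0371) against 2.49 (SE 0.499). It was still more than its SE above 1.24, the level set for this test. Glycam1 is a single gene and was weak on several arrays, so the covariate may correct for lymph node tissue only in part. Such tissue therefore stays open as a source of the rise. Immunization as the source stays open. Against vehicle infected lungs the value with the covariate was 1.78 (SE 0.33, adjusted p = 0.000891). But at 7 days Ighg3 did not pass against non-infected lungs, either without the covariate (1.04, SE 0.499, adjusted p = 0.599) or with it (0.95, SE 0.31, adjusted p = 0.291). A further probe set of Ighg3 differed by 0.55 from non-infected lungs and did not pass.

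Clock genes were shifted in co-immunized 7 d against non-infected lungs, 7 of them called: the activators Arntl and Npas2 and the repressor Nfil3 down, and Dbp, Hlf, Per2 and Per3 up. RNA quality is argued against: with the 3-prime to 5-prime ratio as a covariate all 7 stayed called, with a median size of 1.75 against 1.73. Infection alone, as it was in vehicle infected lungs at 48 hours, is argued against for 6 of them. In those lungs these 6 moved by at most 0.486 in the same direction (Npas2), with Nfil3 going the opposite way by 2.43. Infection alone stays open for Per2, which rose there by 1.32 (adjusted p = 0.000252). No vehicle infected lungs were collected at day 7, so infection alone at that time was not tested. A different hour of collection could shift the same genes in these directions. The labels give no hour, so it cannot be told apart from immunization. In co-immunized lungs at 48 hours all 7 lay in the same direction with a median of 1.17, and 5 were called. Day 7 alone is thus argued against for these 5, though both comparisons share the non-infected arrays. For Hlf and Nfil3, which did not pass at 48 hours (adjusted p = 0.0825 and 0.0772 by limma), day 7 stays open.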

How the results depend on the processing

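The alternatives without 4 arrays carrying thymocyte or skeletal muscle genes and with 3 tissue covariates were chosen after the result was seen; the others were planned. A minimum signal of a linear scale was not run, since the values were already on the log2 scale. Of 210 alternative counts 153 stayed within 1.5 times the value reported and 57 did not; of 3951 values of named genes 3651 kept direction and side of the threshold, 271 lost the call, 13 gained it and 16 changed sign; of 1069 list values 974 kept both, 94 lost the call and 1 gained it. In vehicle infected against non-infected lungs no named gene lost its call. Except where construction is named, the cause was not tested. Weak signals near background limit what arrays can show, and without the filter 18193 genes were tested in place of 14849.

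Leaving out each array in turn gave 3019 to 4669 genes in vehicle infected against non-infected lungs, 2588 to 4930 in co-immunized 48 h against vehicle infected, 42 to 471 in co-immunized 48 h against non-infected, 4 to 13 in co-immunized 7 d against non-infected and 1 to 28 in 7 d against 48 h. The lowest came without non-infected replicate 3, vehicle replicate 5, co-immunized 48 h replicate 4, 7 d replicate 4 and 7 d replicate 3. For co-immunized 48 h against non-infected lungs the count was 63, 87, 131 and 196 without non-infected replicates 5, 3, 4 and 2, and 98 and 155 without co-immunized replicates 3 and 1. For 7 d against non-infected lungs it was 6, 7 and 8 without 7 d replicates 1, 2 and 3, 7 without non-infected replicate 2 or 3 and 8 without non-infected replicate 5; for 7 d against 48 h it was 9 without 7 d replicate 1 or 2, 12 without 7 d replicate 4, and 8 and 11 without co-immunized 48 h replicates 1 and 4.

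With all kept probe sets tested separately, 6966 were called in vehicle infected against non-infected, 6720 in co-immunized against vehicle infected and 13 in 7 d against 48 h, the first pair by construction, since 34104 were tested. A 2-fold minimum left 1313, 1246 and 110 in the comparisons at 48 hours, also by construction. From the arrays of the 2 groups alone the counts were 2065 in co-immunized against vehicle infected, 1382 in co-immunized 48 h against non-infected, 22 in 7 d against non-infected and 2 in 7 d against 48 h. In the last 3 of these, in that order, array weights gave 1344, 65 and 110, and a prior variance without trend 160, 8 and 11. RNA quality as a covariate gave 632 and 20 in the comparisons of co-immunized 48 h and 7 d with non-infected lungs. Quantile normalization gave 21 in 7 d against non-infected lungs, and the mean of probe sets 14 in 7 d against 48 h. Without the 4 arrays the counts were 36 in co-immunized 48 h against non-infected and 8 in 7 d against 48 h. With the 3 tissue covariates they were 2102 in co-immunized against vehicle infected, 17 in co-immunized 48 h and 21 in 7 d against non-infected, and 2 in 7 d against 48 h.

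With replicate numbers as a block, the replicate block fit gave 89 genes in co-immunized 48 h and 5 in 7 d against non-infected lungs, and moved no other count of genes by over 1.5 times (3674, 2787 and 18); of the list calls described it ended that of acute phase genes at 7 d (adjusted p = 0.0646). The numbers do not appear to pair the arrays: of 25 same-numbered pairs 5 correlated over 0.1 in their deviations from the group means and 14 lay under 0 (median -0.0236, range -0.316 to 0.345, against 0.00416 for other pairs), and 3 of 18 arrays correlated best with their own number.

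Camera with an estimated correlation called 11, 0, 0, 1 and 2 lists in the 5 comparisons in the order of the report, and fry 2, 1 and 2 in the last 3. The overlap of infection and immunization changes was 1451.5 (median) with the vehicle arrays split between the comparisons, which leaves 2 or 3 arrays in each.

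In vehicle infected against non-infected lungs, Sftpc and Scgb1a1 were near 0 and changed sign. They stood at -0.0468 and -0.0595 with quantile normalization, -0.0592 and -0.10 with array weights, -0.13 and -0.17 with RNA quality, -0.0638 and -0.11 without the 4 arrays, and ranged from -0.024 to 0.19 and from -0.066 to 0.16 without each array in turn. Ighm stood at 0.45 without probe sets that can cross-hybridize.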

Other observations

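The 3 gene lists in this part were fixed before the data were examined, and they were picked for description after the result was seen.

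In vehicle infected against non-infected lungs (n = 5 and 5), NF-kB feedback and response genes rose in 12 of 18 measured members by either adjustment. Among them were P-selectin (Selp), an adhesion molecule of endothelium and platelets, by 2.27 (SE 0.314), and Tnfaip3, which restrains NF-kB signalling, by 2.01 (SE 0.257). In co-immunized against vehicle infected lungs at 48 hours (n = 4 and 5), 14 of the 18 were lower (15 adjusted over the list alone), with Selp down (-2.35, SE 0.333) and Tnfaip3 down (-2.16, SE 0.273). The adjusted p of these set calls with an estimated correlation was 0.0597 and 0.091, so both were lost. No member differed between co-immunized 48 h and non-infected lungs by either adjustment (list median 0.00775).

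Of 17 coagulation and fibrinolysis genes 7 rose and 1 fell in vehicle infected lungs (8 and 2 adjusted over the list alone), with coagulation factor X (F10) at 2.64 (SE 0.296). In co-immunized against vehicle infected lungs 9 were lower (10 adjusted over the list alone), including F10 (-2.12, SE 0.314) and the tissue plasminogen activator gene Plat (-2.03, SE 0.321). With an estimated correlation both set calls were lost (adjusted p = 0.385 and 0.217). The first was also lost with quantile normalization (adjusted p = 0.0532) and without non-infected replicate 1 or 2 or vehicle replicate 3 or 4 (up to 0.0721), and both were lost without the 4 arrays with other-tissue genes (0.0992 and 0.0624).

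Extracellular matrix and repair genes went both ways and were not called as a list in either comparison. In vehicle infected lungs 4 of 24 rose and 8 fell (5 and 9 adjusted over the list alone). The metalloproteinase inhibitor Timp1 rose by 4.41 (SE 0.340) and lysyl oxidase (Lox), which cross-links collagen, by 2.17 (SE 0.192). In co-immunized against vehicle infected lungs 4 were higher and 7 lower (5 and 7 adjusted over the list alone), with Timp1 down (-3.17, SE 0.361) and Lox down (-2.90, SE 0.203).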
